A study of Zea mays with 6 samples.

How the data were processed

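RNA was measured in 2 to 3 mm tassels of maize in the B73 background, in 3 wildtype and 3 rel2-ref mutant samples with tissue of 5 plants each. Per the labels' protocols, tissue was frozen in liquid nitrogen, total RNA was extracted on columns with a DNase step, and stranded TruSeq libraries were made. TopHat2 2.1.1 and Cuffdiff 2.2.1 are named in the submitters' processing notes. The genome build, the gene annotation, the library normalization of Cuffdiff and the depth per library are not given in the sources used here. No precision from read counts can therefore be stated.

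A single table was used. Per the file headers it is Cuffdiff's table of gene differences, in which the authors reduced the 3 samples of a genotype to 1 FPKM value. The deposited log2 fold change is the log2 of mutant over wildtype FPKM with no pseudocount, and it matched the FPKM ratio within 1.31e-05 wherever both values were above 0 and the test had not failed. The deposited score of each gene is Cuffdiff's test statistic. The deposited p-value has a floor of 5e-05, which 483 called genes share, so that they cannot be ranked by p. The deposited q-value equals the Benjamini-Hochberg adjustment of p over the 23348 tested genes within 5.27e-07, and the authors' own column of significance is q under 0.05 in every row. Of 39283 genes, 15933 were not tested by Cuffdiff and 2 had a failed test. Averaging by Cuffdiff removes the spread between samples from the levels, and FPKM are relative to the library, so a few abundant transcripts can move all others. The FPKM summed over genes were 784038 in wildtype and 774324 in rel2-ref, and the median log2 fold of tested genes was 0.01.

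Because no value per sample was used, no test across samples was made. Calls are genes with a deposited q under 0.05. Fold changes were computed as log2((mutant FPKM + 1)/(wildtype FPKM + 1)). The test planned for such a table was applied: Fisher's exact test (two-sided) of list members among genes called higher, and separately lower, against all tested genes, with Benjamini-Hochberg adjustment over all 92 tests of the 46 lists with at least 5 tested genes. The median log2 fold of a list was also placed among 10000 random lists of the same size, drawn from 20 bins of mean FPKM. Counts adjusted over the list alone use Benjamini-Hochberg over the deposited p-values of a list's tested genes. They were planned only for a table with values per sample and are not adjusted across lists. A list rich in small p-values has a laxer limit, so these counts are descriptions. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

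Symbols came from the RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, used for names and not for positions. It matched 18995 of the gene IDs, 520 of them to over 1 record. A symbol or synonym was found for 2240 of the tested genes and 211 of the called ones. Names follow the commonly used synonym where a gene has several. The comparison, its test, the alternatives, the rule for named genes and the themes of most gene lists were chosen before the data were examined. The lists fixed then by descriptions could not be matched, since the gene table carries none. They were restated as patterns of symbols after the overall counts of calls were known and before the value of any single gene was looked at. The lists for LBD, bZIP, GLK and GARP, GRF, OFP, ZCN, aquaporins, glutathione transferases, chromatin, microRNA precursors and cell number regulators were added at that step. Symbol patterns can take in a gene of another kind: the called member of the seed storage list is a hemoglobin gene that shares a synonym with a globulin, and ARF symbols can name auxin response factors or ADP-ribosylation factors. Patterns can also leave a gene out: dbf1, called higher, is not in the AP2/ERF list, which holds dbf2. Counts of members are thus counts of matched symbols and not of whole families.

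The rule for named genes took rel2 and other TOPLESS-type genes; the 10 higher and 10 lower called genes with the largest log2 fold that had a symbol and at least 5 FPKM in the higher genotype; up to 4 called members per list by smallest q, or the 2 of highest mean FPKM where none was called; and each called gene of the architecture and KNOX lists. A few other members are named to complete a count or as examples of uncalled genes, chosen after their values were seen. Alternatives were pseudocounts of 0.1 and 5 FPKM, no filter on low values, a minimum of 5 FPKM, centring on the median, q under 0.01, and q under 0.05 with at least a 2-fold change. Added after the data were seen were a background of genes with a symbol, and leaving out genes within 10 Mb of rel2 or on chromosome 10.

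The list tests were tested on simulated data. With higher calls drawn at random over the 23348 tested genes and 20-gene lists planted with a 40% share of higher calls, 97.0% of 100 planted lists were recovered, and with a 20% share 53.0%. At the 20% share, 0.122% of 1640 unplanted tests passed. The simulated lists were random draws from all tested genes, with independent calls. The real lists hold only genes with a symbol, which were called more often (9.42% against 4.37%), and their members may change together. The rate of false passes among the real lists is thus not known from this simulation. For the comparison of list medians with matched random lists, a shift of 0.3 on the log2 scale put 100% of 200 simulated lists of 20 genes above the 95th percentile, and 6.5% of 200 unshifted ones. Here the log2 folds were first shuffled over the genes, which breaks any link between fold and mean FPKM. The matching on mean FPKM was thus not put to the test. Each gene of a shifted list moved by the same amount, unlike the members of a real list.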

Results

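RNA was sequenced from young maize tassels, the male inflorescences, collected when they were 2 to 3 mm long. Plants carrying the rel2-ref allele of ramosa1 enhancer locus2 (rel2), which encodes a TOPLESS-type transcriptional corepressor, were compared with wildtype plants. Both genotypes were in the inbred line B73 and were grown in the field. There were 3 samples per genotype, each holding tissue from 5 plants. The deposited values are FPKM, fragments per kilobase of transcript scaled to the sequenced fragments, with 1 value per genotype for each of 39283 genes. Values of single samples were not analysed here, so no standard deviation is given for any level. The depth of the libraries is unknown. The only account of error used here is the p-value and q-value that Cuffdiff gave each gene in the authors' deposited table. A gene is called higher or lower here when its deposited q is under 0.05, and fold changes are log2((mutant FPKM + 1)/(wildtype FPKM + 1)), which understates the change of low genes. The p-values rest on Cuffdiff's own model of these samples, and a gene's spread between the samples was not computed. Nothing in the labels says whether the samples of a genotype came from separate plots or days. The p-values therefore cannot be taken to cover variation between plots or days.

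The rel2 transcript itself was present in both genotypes. Its level was 102 FPKM in wildtype and 87.3 FPKM in rel2-ref tassels, a log2 fold of -0.23, and it was not called (q = 0.656 in the authors' deposited table). The gene, GRMZM2G042992, lies on chromosome 10 from 76650033 to 76659099 in the coordinates of the authors' deposited table, whose genome build is not given in the sources used here. A lesion can leave the transcript level as it was, so this value does not check the genotype labels. The other TOPLESS-type genes with a symbol, RELK2 and RELK3, were not called either. RELK2 had 55.8 FPKM in wildtype and 59.7 FPKM in the mutant (q = 0.955 in the authors' deposited table), and RELK3 had 77.7 and 86.6 FPKM (q = 0.838 in the same authors' deposited table).

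The comparison of the genotypes asked which transcripts depend on rel2 in the developing tassel. Genes that act in branching and meristem fate stood among the called genes on both sides: ra3 and ra1, which limit tassel branching, fell, while the SBP-domain genes ub3, ub2 and tga1 rose. In the authors' deposited table q was 0.00242 for each of ra3, ra1 and ub3. It was 0.034 for ub2 and 0.0458 for tga1, so these 2 calls are weaker and do not hold at q under 0.01. The transcript of ra3, a trehalose-6-phosphate phosphatase, went from 88.8 to 22.9 FPKM. That of ra1, a zinc-finger transcription factor, went from 14.2 to 4.28 FPKM. The transcript of ub3 went from 175 to 305 FPKM. In all, 1133 of 23348 tested genes (4.85%) had q under 0.05 in the authors' deposited table, 534 higher and 599 lower in rel2-ref. Changes were mostly moderate, with a median log2 fold of 0.83 among the called higher genes and -0.79 among the called lower ones. At least a 2-fold change was seen in 301 called genes, 166 higher and 135 lower. At an unadjusted p under 0.05 the authors' deposited table holds 3101 genes, where 1167 would be counted if no gene differed. The balance of directions depended on the setting: among genes with at least 5 FPKM in either genotype, 452 were higher and 416 lower, and 334 were higher and 311 lower at q under 0.01 in the authors' deposited table. With a pseudocount of 0.1 FPKM the 2-fold set held 252 higher and 314 lower genes, and with 5 FPKM it held 58 and 25.

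**Figure D1:**
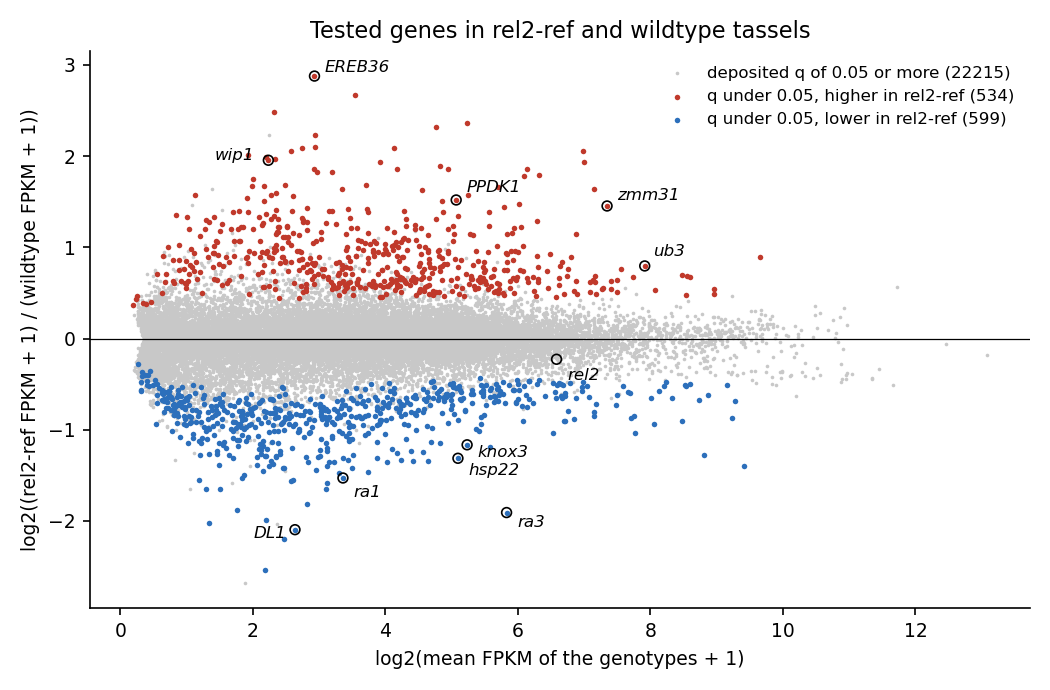
Log2 fold of rel2-ref over wildtype FPKM (y axis, pseudocount 1 FPKM) against log2 of the mean FPKM plus 1 (x axis) for the 23348 tested genes. Each point is a gene, coloured where its q in the authors' deposited table is under 0.05 (534 higher, 599 lower), and circles mark named genes, with rel2 at -0.23 among the uncalled genes.

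The called genes with the largest changes, at 5 FPKM or more in the higher genotype and with a symbol, covered several kinds of gene. On the higher side, EREB36, an ERF-type transcription factor gene, went from 0.824 to 12.4 FPKM (log2 fold 2.88). The wound-induced proteinase inhibitor gene wip1 went from 0.927 to 6.47 FPKM (1.96), FIP1 from 5.21 to 18.9 FPKM (1.68), and PPDK1, for pyruvate orthophosphate dikinase, from 16.3 to 48.7 FPKM (1.52). The potassium transporter gene HAK10 rose by 1.51 on the log2 scale, the MADS-box gene zmm31 by 1.45, the aquaporin gene TIP2-1 by 1.36, dbf1 by 1.34, bZIP17 by 1.24 and MAPKKK by 1.21. On the lower side, IIG1 went from 8.08 to 0.979 FPKM (-2.20) and the YABBY gene DL1 from 9.07 to 1.36 FPKM (-2.10). ACO20, of the family that makes ethylene from its precursor, went from 6.34 to 0.854 FPKM (-1.98). After ra3 (-1.91) and ra1 (-1.53) came knox8 (-1.45), cl2-1 (-1.44), the cytochrome P450 gene CYP78A53 (-1.42), yab14 (-1.42) and por (-1.36). Each of these 20 genes had q under 0.05 in the authors' deposited table. Most of the response has no name here: 922 of the 1133 called genes (81.4%) carried no symbol.

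Among 33 tested genes of inflorescence architecture, 6 rose, 5 fell and 22 were not called. The genes that rose were ub3 (log2 fold 0.80), tga1 (0.68), dlf1 (0.67), sid1 (0.66), ub2 (0.50) and ids1 (0.49). Of these, dlf1 is a bZIP gene of the floral transition, and ids1 and sid1 are AP2 genes that act in spikelet meristem fate. The genes that fell were ra3 and ra1, bd1 (-1.55), an ERF gene of spikelet meristem identity, bif2 (-1.20), a PINOID-like kinase gene of axillary meristem initiation, and td1 (-1.20), a CLAVATA1-like receptor kinase gene. The level of bd1 was low in both genotypes, 2.37 and 0.153 FPKM. Members not called included fea3 (-0.45), spi1 (-0.47), tb1 (-0.24), fea2 (-0.09) and wus1 (0.05). By Fisher's exact test (two-sided, against all tested genes, adjusted over 92 tests), the list held more higher calls (q = 0.0021) and more lower calls (q = 0.012) than the rest. As a whole the list lay low, with a median log2 fold of -0.13 at percentile 0.09 of 10000 random lists matched on mean FPKM, and so its median and its higher calls point in opposite directions. The counts were the same, 6 and 5, when adjusted over the list alone. Genes with a symbol were called more often (9.42%) than genes without one (4.37%). Against a background of genes with a symbol, a choice made after the data were seen, the higher calls kept q = 0.0358 and the lower ones had q = 0.226.

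**Figure D2:**
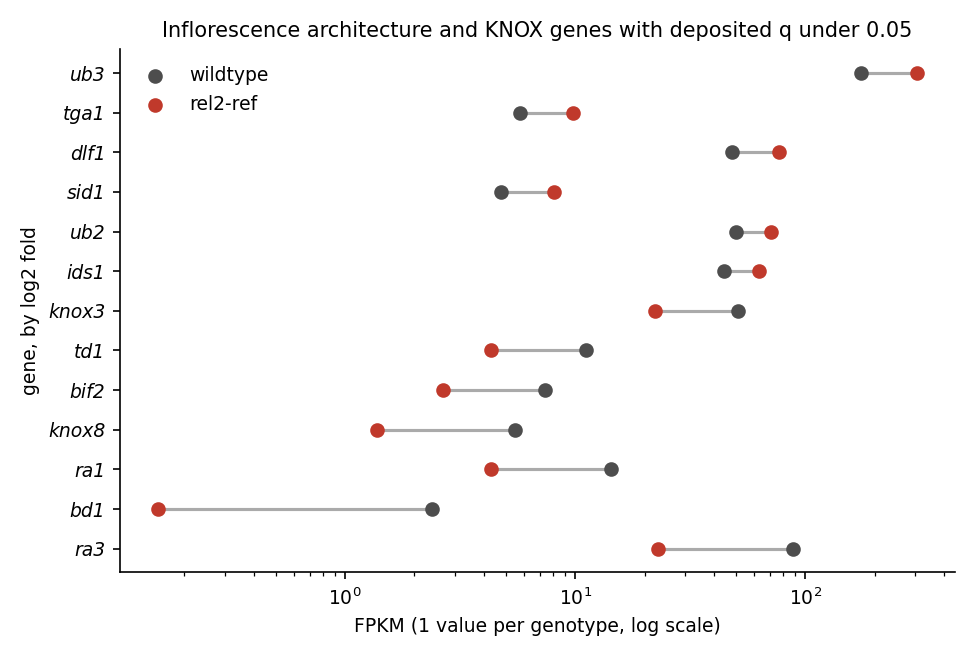
FPKM in wildtype (grey) and rel2-ref (red) tassels for the 11 inflorescence architecture genes and the 2 KNOX genes with q under 0.05 in the authors' deposited table. The x axis is FPKM on a log scale with 1 value per genotype, and genes are ordered by log2 fold, from ra3 (88.8 and 22.9 FPKM) at the bottom to ub3 (175 and 305 FPKM) at the top.

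Several transcription factor lists held more higher calls than the rest of the genes. Of 36 AP2/ERF genes, 9 rose and 2 fell (q = 8e-06 for higher calls in the Fisher test, and 0.000853 against genes with a symbol); examples are EREB36, DBP4 (log2 fold 0.94), EREB179 (0.94) and DREB2A (0.76), beside ids1 and sid1. Of 22 SBP genes, sbp21 (0.64), ub2, ub3 and tga1 rose and sbp1 (-0.74) fell, with q = 0.012 for higher calls and q = 0.117 against genes with a symbol. Of 20 MADS-box genes, 4 rose and 1 fell (q = 0.0109, and 0.093 against genes with a symbol). Those that rose were zmm31, from 86 to 237 FPKM, zmm19 (0.94), MADS34 (0.73) and zmm24 (0.57). Of 17 Aux/IAA genes, the family of auxin-labile repressors, AUX9 (0.89), AUX17 (0.71), AUX3 (0.57) and AUX6 (0.54) rose, while AUX35 (-0.73) and AUX10 (-0.72) fell. The q for higher Aux/IAA calls was 0.00779, and 0.0671 against genes with a symbol. The 18 tested genes with an ARF symbol, which can stand for auxin response factor or ADP-ribosylation factor, so that the list may mix both, had no call. In that list arf1 stood at 329 and 330 FPKM and ARF13 at 167 and 192 FPKM. Adjusted over the list alone, the higher and lower calls were 11 and 3 for AP2/ERF, 5 and 1 for SBP, 5 and 3 for MADS-box, and 5 and 3 for Aux/IAA.

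Of 16 genes of the YABBY and leaf polarity list, DL1 (log2 fold -2.10), yab14 (-1.42) and YAB6 (-0.63) fell and none rose. The Fisher test gave q = 0.0478 for lower calls, which was lost among genes at 5 FPKM or more (q = 0.0818) and against genes with a symbol (q = 0.319). Adjusted over the list alone, the same number, 3, were lower. Of 20 KNOX and WOX homeobox genes, knox8 and knox3 fell, the latter from 51.0 to 22.2 FPKM, while KN-1 (-0.29) was not called. The list as a whole did not pass (q = 0.314 for lower calls), and adjusted over the list alone 2 were lower. HB21 (-1.10), HB115 (-0.94), HB127 (-0.81) and HDZIV8_OCL8 (-0.52) fell among 35 HD-ZIP and other homeobox genes, with 1 gene higher and q = 0.0686. OFP16 (-0.80) and OFP24 (-0.68) fell among 7 OFP genes (q = 0.0686). Adjusted over the list alone, 7 homeobox and 3 OFP genes were lower.

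Stress genes were called on both sides. Of 25 heat shock genes, 6 fell and none rose: hsp22 went from 47.7 to 18.6 FPKM (log2 fold -1.31), hsp101 from 20.5 to 9.44 FPKM (-1.04), HSP70 from 149 to 80.3 FPKM (-0.88) and hsp18f from 268 to 146 FPKM (-0.87). The Fisher q for lower heat shock calls was 0.00149, and 0.0358 against genes with a symbol. In contrast, 3 of 6 dehydrin and LEA genes rose (q = 0.00416, and 0.0358 against genes with a symbol): EMB5 (1.20), DHN1 (0.90, at 0.0865 and 1.03 FPKM) and dehydrin3 (0.54). Of 18 aquaporin genes, 5 fell and 1, TIP2-1, rose (q = 0.0021 for lower calls, and 0.0358 against genes with a symbol). PIP1-2 (-0.68) and PIP2-2 (-0.56) of the plasma membrane fell, as did NIP2-3 (-1.08). Of 23 glutathione transferase genes, GST25 (-1.09), gst5 (-0.87) and GST3 (-0.79) were among 4 that fell, and gst20 (1.04) rose (q = 0.0198 for lower calls, and 0.228 against genes with a symbol). Adjusted over the list alone, 6 heat shock, 6 aquaporin and 7 glutathione transferase genes were lower and 3 dehydrin and LEA genes were higher.

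The defence and secondary metabolism list went both ways, with 5 of 31 genes higher (q = 0.00839) and 5 lower (q = 0.0109). Neither call passed against genes with a symbol (q = 0.093 and 0.194), and the list median of -0.20 was below 0, opposite to its higher calls. The benzoxazinoid synthesis gene BX4 fell from 87.3 to 46.3 FPKM (log2 fold -0.90), while the proteinase inhibitor genes wip1 and MPI rose. TPS3 (0.78) rose too, a gene matched by its symbol alone, which does not settle what kind of enzyme it encodes. The terpene synthase gene TPS17 fell (-0.83). Of 40 jasmonate synthesis and signalling genes, 5 fell and 2 rose (q = 0.0242 for lower calls, and 0.344 against genes with a symbol). The lipoxygenase genes lox11 (-1.21) and lox10 (-0.94, from 348 to 181 FPKM) and the allene oxide synthase gene aos2 (-0.58) fell, and TIFY25 (0.77) rose. The median log2 fold of the jasmonate list was 0.03 and its mean -0.05, of opposite sign. Among 31 histone genes, 4 were called lower and none higher (q = 0.0478, and 0.415 against genes with a symbol): H3C4 at GRMZM2G355773 (-0.70) and at GRMZM2G376957 (-0.52), H3C2 (-0.62) and H4C7 (-0.51). Histone genes can have near-identical copies among which reads are split. This was not checked here, so the values of single histone genes are uncertain. Adjusted over the list alone, 5 defence genes were higher and 6 lower, 2 jasmonate genes were higher and 6 lower, and 14 histone genes were lower.

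**Figure D3:**
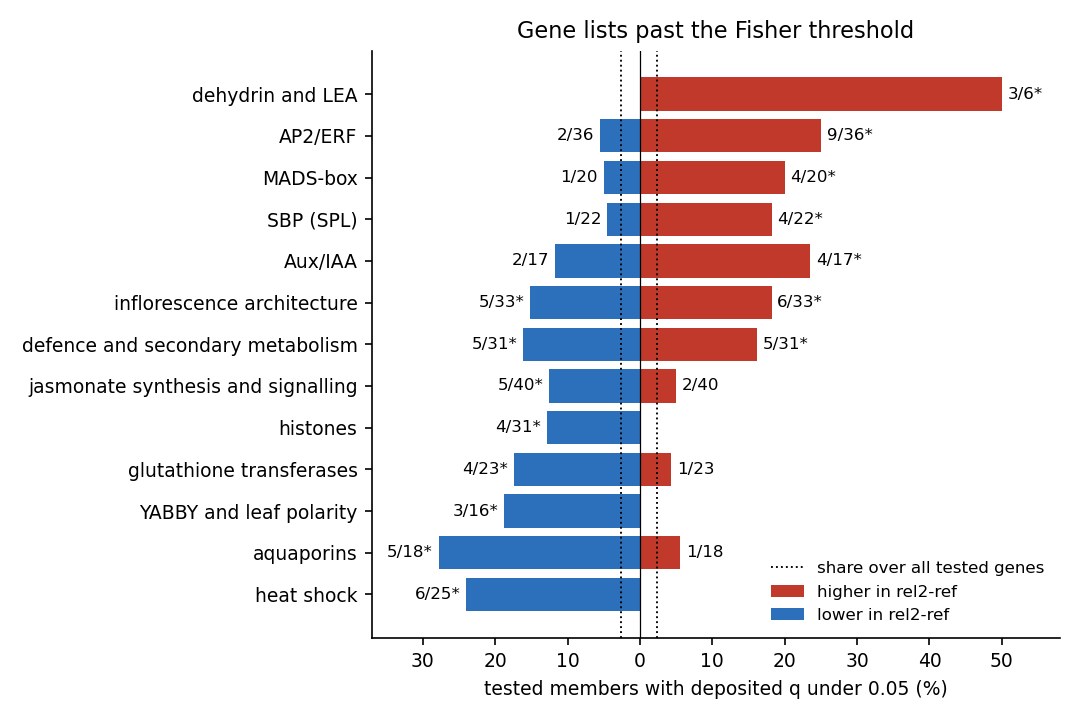
Share of tested members called higher (red, to the right) or lower (blue, to the left) in rel2-ref, in percent, for the lists past the threshold in the Fisher test. Labels give called over tested genes, an asterisk marks an adjusted q under 0.05, and dotted lines mark the shares over all tested genes. Dehydrin and LEA genes (3 of 6 higher) stand at the top and heat shock genes (6 of 25 lower) at the bottom.

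In total, 46 lists had at least 5 tested genes, and 7 passed for higher calls and 8 for lower calls, with inflorescence architecture and defence in both. Lists share members: ub2, ub3 and tga1 count as SBP and architecture genes, and ids1, sid1 and bd1 as AP2/ERF and architecture genes. Of these 15 calls of lists, 5 passed against genes with a symbol, 9 passed with genes at q under 0.01 in the authors' deposited table, and 1 passed when calls also needed a 2-fold change, that for lower architecture genes. The 6 lost at q under 0.01 in the authors' deposited table were the higher calls of the SBP and architecture lists and the lower calls of the YABBY, aquaporin, histone and jasmonate lists. No gene was called in 11 lists. These included 24 cyclin and cell cycle genes, with pcna2 at 399 and 305 FPKM and cyclin4 at 133 and 125 FPKM, 53 ribosomal protein genes, with RPP1A at 1108 and 1223 FPKM and RPL32 at 915 and 1005 FPKM, and 49 chromatin genes, with MNB1B at 2253 and 1709 FPKM and hmg2 at 491 and 431 FPKM.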

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

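The tests on heat shock genes and on the cell cycle, and the windows other than 10 Mb, were chosen after the results were seen.

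In 2 abundant genes the deposited Cuffdiff test failed, so they entered no comparison although their values lie far above 0. GRMZM2G124317 on chromosome 9 had 1198 FPKM in wildtype and 1415 FPKM in rel2-ref, and hdt103, a histone deacetylase gene at GRMZM2G159032 on chromosome 6, had 513 and 620 FPKM in the authors' deposited table.

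Genes near rel2 were called more often than genes elsewhere. Within 10 Mb, 14 of 153 tested genes (9.15%) were called, against 4.82% of the other genes. The odds ratio was 1.99 (95% interval 1.14 to 3.45, Fisher's exact p = 0.0213). A chromosome segment from another line carried along with rel2-ref would give such an excess. Within 2 Mb, 6 of 35 genes were called, an odds ratio of 4.07. Fisher's exact p was 0.00625 within 2 Mb, 0.0951 within 5 Mb, 0.0408 within 20 Mb and 0.196 within 30 Mb. Genes called with at least a 2-fold change made up 1.31% within 10 Mb, against 1.29% elsewhere. Their share was larger within 2 Mb (2.86%, 1 gene) and 5 Mb (2.67%, 2 genes). It was also larger within 20 Mb (2.37%, 7 genes) and 30 Mb (2.00%, 8 genes), against 1.28% elsewhere. The 2-fold shares were not tested. Of the 14 genes, 10 were lower and 4 higher; GRMZM2G171236, at 0.472 Mb, fell by 2.54 on the log2 scale, and NAC61, at 1.49 Mb, was higher (the first of them named after its value was seen), and such a segment may account for these calls. For segments elsewhere, the largest share of called genes in a 5 Mb window was 17.9%, at the median of 1000 shuffles (17.9%, permutation p = 0.544). The 95th percentile of the shuffles was 23.8%, above the 17.1% called within 2 Mb of rel2. The scan could thus miss an excess as strong as that near rel2, and segments elsewhere stay open. The windows with the 2 largest shares lie side by side on chromosome 6, at 30 to 35 Mb (5 of 28 genes) and 35 to 40 Mb (5 of 31). Runs of windows were not tested. Regulation of neighbouring genes by rel2 itself was not tested and stays open.

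The fall of ra1 and ra3 beside the rise of ub2, ub3 and tga1 was weighed against a segment linked to rel2 and a general loss of dividing cells. The rises of ub2 (q = 0.034) and tga1 (q = 0.0458, both in the authors' deposited table) are the weaker calls of this pattern. None of the 5 genes lies on chromosome 10 (0 of 5), so none can itself be part of a segment linked to rel2. This follows from their map positions and not from the expression values. Effects of such a segment on genes elsewhere were not tested, and segments on other chromosomes stay open. Chromosome 7, which holds ra1 and ra3, had the largest share of called genes of all chromosomes (5.85%, Fisher's exact p = 0.0419, adjusted q = 0.419). For a lower share of dividing meristem cells as a whole, a fall of the cell cycle list by over 0.5 on the log2 scale was looked for. The median log2 fold of that list was -0.10 with an interquartile range of 0.28, so the list did not fall as far as ra1 (-1.53). The limit of 0.5 was a choice, and how far a loss of dividing cells would move the list is not known, so such a loss is not decided. A loss of cells in S phase also stays open. The cell cycle median lay at percentile 0.39 of 10000 matched random lists, pcna2 had a log2 fold of -0.38, and all 31 histone genes were lower (median -0.40). A change in the share of one meristem type, which the mutant could have through altered branching, stays open, as does direct dependence on rel2; neither can be separated in whole tassels.

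Whether the fall of heat shock genes belonged to a general fall of stress genes stays open. The dehydrin and LEA list went the other way, with a median log2 fold of 0.35 and 3 of 6 genes higher, as did the proteinase inhibitor genes wip1 (1.96) and MPI (0.69), but the list's interquartile range was 0.77 and one of the 3, DHN1, is at 0.0865 and 1.03 FPKM. Glutathione transferase genes fell in 4 cases and rose in 1, and the defence list, with 5 genes higher and 5 lower, had a median of -0.20 at percentile 0.02 of matched random lists. The heat shock list had a median log2 fold of -0.13 and a mean of -0.26, and 19 of its 25 genes were not called. The median of 10000 random lists matched on mean FPKM was 0.00561, so genes of the same abundance as a set did not fall. Since the median over all tested genes was 0.01, a value near 0 was to be foreseen, and it does not serve as a test of a shift shared by such genes. A difference in field temperature or time of harvest between the genotypes may also lie behind the fall of heat shock genes. The labels give neither, so this was not tested, and a dependence on rel2 stays open too.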

How the results depend on the processing

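The settings without genes near rel2 and the background of genes with a symbol were chosen after the data were seen. The count of called genes moved from 1133 to 645 (334 higher, 311 lower) at q under 0.01 and to 301 (166 higher, 135 lower) with a 2-fold change also required, in both through the stricter threshold itself. Between 868 and 1119 genes were called with no filter, a minimum of 5 FPKM, or without genes within 10 Mb of rel2 or on chromosome 10; the share of higher calls was 47.1% as deposited, 52.1% with the minimum of 5 FPKM and 51.8% at q under 0.01. Called genes with at least a 2-fold change numbered 566 with a pseudocount of 0.1 FPKM and 83 with 5 FPKM, since the pseudocount shrinks the change of low genes; 44.5% and 69.9% of them were higher, against 55.1% with 1 FPKM. The 15 list calls became 9 at q under 0.01 and 1 with a 2-fold change, where only the lower calls of inflorescence architecture passed, with fewer called genes in both. They became 5 against genes with a symbol, which are called more often: higher AP2/ERF, dehydrin and LEA and inflorescence architecture, and lower aquaporin and heat shock calls. With no filter the higher SBP call was lost (q = 0.218) and lower HD-ZIP and other homeobox calls passed (q = 0.02). With the minimum of 5 FPKM the YABBY call was lost and the dehydrin and LEA list, left with fewer than 5 tested genes, gave no value. The rel2 log2 fold stayed between -0.22 and -0.23 under both pseudocounts and centring. Centring moves each gene by the same 0.01 on the log2 scale, too little to test any call. No paired analysis was possible because there is 1 value per genotype; for the same reason leaving out replicates, quantile normalization, limma and other splits of the samples were not run, and a count test was not used on FPKM. Depth is unknown, so it cannot be said which uncalled genes were too thinly covered to be called.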

Other observations

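Other lists had few calls. None of those with at least 5 tested genes passed the Fisher test, and smaller lists were not tested. Among hormone genes, the DELLA gene D8 fell (log2 fold -0.73) and Dwarf1, of gibberellin synthesis, rose (0.76), so that the gibberellin list held 1 higher and 1 lower of 5 genes. The cytokinin receptor-type gene HK1b1 (-0.86) and the cytokinin oxidase gene CKX10 (-0.93) fell among 30 cytokinin genes. Of 20 abscisic acid genes, the receptor genes PYL9 (-1.05) and PYL10 (-0.72) fell, and SnRK2.1 (0.68) and asr1 (0.83) rose. ACO20 was the called member of 11 ethylene genes and bif2 of 9 genes of auxin synthesis and transport. In the list of CLE peptides, td1 was the called member of 3 tested genes, although it is a receptor kinase gene and not a peptide gene. Neither the 3 brassinosteroid genes, with DWF1 at 215 and 207 FPKM and na1 at a log2 fold of -0.25, nor GH3, the single tested gene of the SAUR and GH3 list (13.0 and 16.8 FPKM), was called.

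Among other transcription factor lists, bZIP17 (1.24), bZIP9 (1.39) and dlf1 rose and 3 genes fell of 34 bZIP genes, and bHLH35 (-0.96) was among 3 lower and 2 higher of 38 bHLH genes. Of 8 GRAS genes, scl1 rose (0.097 and 1.2 FPKM) and D8 fell, with a list median of -0.41 and 5 genes lower when adjusted over the list alone, and the GRF list GRF2 (-0.66), GRF12 (-0.63) and atGRF2 (0.65) of 17. Myb36 (0.96) and MYB59 (-0.92) were called of 38 MYB genes, NAC1 (0.75) and NAC61 (0.57) of 19 NAC genes, and WRKY30 (1.20) of 17 WRKY genes. No call was made among 8 TCP genes (BAD1 -0.26, TCP12 -0.12), 9 GLK and GARP genes (GLK47 -0.47, GLK17 0.12), 5 GATA genes (GATA17 and GATA5, -0.01 and 0.06), 5 LBD genes (LOB15 0.64, LOB14 0.20), 7 ZCN genes (ZCN3 -1.02, ZCN14 -0.01), 7 cell number regulators (CNR8 0.41, CNR6 -0.05) or 20 microRNA precursors (zma-MIR162 1.10, zma-MIR160d -0.30).

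Markers of other tissues and of metabolism had few calls. PPDK1 and PPDK2 (0.81) rose of 10 green leaf genes, the meiotic gene Dmc1 (1.14) of 6 anther genes, sus2 (0.56) of 19 sucrose and starch genes, and a hemoglobin gene, HB (1.21), of 5 genes matched as seed storage. PPDK1 and PPDK2 both carry a synonym of the cyppdk type and need not mark green leaf. The other 8 green leaf genes were not called, and the median log2 fold of that list was 0.000669. HDZIV8_OCL8 fell of 13 epidermis and cuticle genes, CesA12 (-0.47, at 0.532 and 0.107 FPKM) of 4 vascular genes, Cel21 (-1.30) of 15 cell wall loosening genes and PAL1 (-0.71) of 8 lignin and phenylpropanoid genes. PER1, the single tested peroxidase gene, had 15.1 and 9.56 FPKM and was not called.

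Several lists that did not pass the Fisher test still had a median log2 fold apart from 10000 random lists matched on mean FPKM. The random lists draw genes independently, while members of a list may change together, and the percentiles are not adjusted over the lists. They describe the lists and are not tests. Under percentile 1 lay GRAS (-0.41), OFP (-0.39), lignin and phenylpropanoid (-0.30), auxin synthesis and transport (-0.25), GLK and GARP (-0.24), epidermis and cuticle (-0.21), HD-ZIP and other homeobox (-0.17), KNOX and WOX (-0.14), bHLH (-0.12) and the cell cycle (-0.10). Above percentile 99 lay cell number regulators (0.33), gibberellin (0.28), NAC (0.21) and ribosomal protein genes (0.08). Median and mean had opposite signs for bZIP (-0.06 and 0.01), anther (-0.11 and 0.11) and ethylene genes (0.06 and -0.20), and also for cytokinin and MYB genes, close to 0.

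Adjusted over the list alone, higher and lower calls were 1 and 5 for GRAS, 4 and 6 for bHLH, 3 and 4 for bZIP, 1 and 3 for GRF, 3 and 1 for NAC, 2 and 1 for WRKY, 1 and 1 for MYB and for ZCN, 0 and 3 for GLK and GARP, 0 and 1 for TCP and 1 and 0 for LBD. They were 3 and 2 for abscisic acid, 2 and 2 for gibberellin, 0 and 2 for cytokinin, 0 and 3 for ethylene, 0 and 1 for auxin synthesis and transport, 3 and 2 for green leaf, 1 and 1 for anther, 2 and 1 for seed storage, 1 and 0 for sucrose and starch, 1 and 3 for cell wall loosening, 0 and 2 for lignin and 0 and 1 for epidermis genes. None was called in this way among GATA, ARF, cell number regulator, microRNA precursor, cell cycle, chromatin or ribosomal protein genes.

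All 31 tested histone genes had a lower value in rel2-ref, from -0.70 to -0.16 on the log2 scale, a pattern noticed after the values were seen. Their median of -0.40 lay below each of 10000 random lists matched on mean FPKM. Near-identical copies can share reads, which was not checked here, so the genes cannot be taken as 31 separate measurements.

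Loss of a repressor could be thought to raise mainly genes with large changes, although more called genes were lower than higher. Among called genes with at least a 2-fold change, 55.1% were higher (exact binomial p = 0.0836, two-sided, genes taken as independent), which decides neither way. At 3-fold or more, a limit chosen after the data were seen, 36 of 48 were higher, but the share at 2-fold ran from 44.5% to 69.9% with the pseudocount.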
